A study of Mus musculus with 6 samples.

How the data were processed

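RNA-seq libraries from the hypothalamus of the mouse line Lhx5-TRAP DT154 fall into 3 libraries of immunopurified RNA (IP) and 3 of unbound RNA. Groups follow the sample type in the labels. The titles call the unbound samples input, a conflict that the labels do not settle, so the second group is called unbound here. The deposited values are raw read counts per gene for each library. Reads were aligned to mm10 with STAR 2.0.0e and counted with HTSeq, per the submitters' processing notes. The gene annotation, the strand setting and the handling of overlapping genes are not given in the sources used here. Reads of a gene and of an overlapping or antisense partner may therefore be mixed, which touches many of the genes named, such as Foxb1, Emx2, Gad1, Prox1, Six3, Zic1, Uchl1, Otx2, Zfhx3, Rpl15, Rpl35 and Peg13.

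Each library listed 32531 gene features. The 5 summary entries and an entry for unknown features, which name no gene, stayed out of library sizes and tests. Of all reads listed, 44.5% ± 0.67 in IP and 32.5% ± 0.62 in unbound libraries aligned to more than one place, 7.74% ± 0.23 and 13.1% ± 0.49 fell in no feature, and 1.61% ± 0.03 and 8.31% ± 1.07 were ambiguous between features (mean ± SD, n = 3). The share assigned to genes was 46.1% in both groups. Gene counts per library were 43440063, 32471045 and 46293837 for IP replicates 1 to 3 and 38541049, 32926146 and 40768577 for unbound replicates 1 to 3. Replicates of a group differed by far more than counting noise, with chi-square values per degree of freedom from 24.4 to 145, so no library was counted as a copy of another.

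Features were matched by symbol or synonym to GENCODE release M21 (GRCm38, the assembly also called mm10), which gave biotype, GC content and position for 23840 of the 32531 features. Features named by an mRNA accession were left under that name.

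Genes were tested with edgeR 4.0.16 in R 4.3.3, with TMM scaling, the filterByExpr defaults (a minimum count of 10 and a minimum total of 15), robust quasi-likelihood fits on group alone, and Benjamini-Hochberg adjustment over the 16991 genes tested at a threshold of 0.05. Standard errors are the log2 fold change divided by the square root of F. The 2-fold filter was applied after the test. The 23 gene lists were fixed before the data were examined, as were the test, the alternatives and the rule for named genes. Some genes are members of more than 1 list. Each list with at least 3 tested members was compared with the other genes by camera (limma 3.58.1, preset correlation of 0.01, log2 CPM with a prior count of 2) and adjusted over the lists. Of the 10 lists called this way, 0 were called with an estimated correlation, and fry, which asks whether the genes of a list move one way on balance, called 11.

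The rule for named genes took Lhx5 and Rpl10a, the 12 largest rises and 12 largest falls, up to 4 members of each list with the smallest adjusted p and members that went the other way, and the 5 most abundant features of each group. The rises and falls needed an adjusted p under 0.05, a mean of at least 5 CPM and groups that did not overlap, and symbols of predicted genes were left out. Other genes named, such as Lhx1, Nts, Tac1, Ghrh, Sst, Gnrh1, Avp, Oxt, Hcrt, Pmch, Ttr, Ppp1r1b, Gpr50, Aldoc and C1ql1, were chosen after their values were seen. Some genes that the rule takes are not reported here.

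Replicate numbers are shared between groups, and the lane in the labels follows them, with lane 4 for replicate 2 and lane 2 for the rest. Over genes, the deviations of same-numbered IP and unbound libraries from their group means correlated at 0.14, 0.16 and 0.21, each library correlating best with its own number. Genes are not independent replicates, deviations from a group mean cancel out within the group, and lane follows the numbers. These values therefore cannot settle that the samples are pairs. By a rule set beforehand (every correlation over 0.1) the numbers were taken as pairs. The pairing comes from this check and not from a label, and the main test does not use it.

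Alternatives were other scalings (size factors of the median-ratio kind, library size alone, pan-neuronal markers), removal of ribosomal protein genes, other count filters, DESeq2 1.42.0, limma-voom, the replicate block, lane as a covariate, removal of a GC trend, and each library left out. No mitochondrially encoded gene was matched under its listed symbol, so that list was not tested. Chosen after the data were seen were fits without the third pair, with lane 2 alone, without the features Rn45s, Mir6236 and Lars2, and a GC correction that keeps each library's mean. The last was added because the planned GC correction had shifted the median, by 0.21 over the 15370 genes it covers, and both are reported. On simulated data for the IP against unbound comparison (16729 genes), the test recovered 39% of 100 genes changed 2-fold and 92% of 100 changed 4-fold. There were 7 false calls among 138, and the changed genes were drawn only from those above a minimum mean level.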

Results

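Translating ribosome affinity purification isolates RNA bound to ribosomes that carry an EGFP-tagged L10a protein, which is made in the cells where a chosen driver gene is active. Here the driver was Lhx5, a LIM-homeodomain transcription factor, in the mouse line Lhx5-TRAP DT154, and the tissue was the hypothalamus of untreated control animals. RNA pulled down with anti-EGFP antibodies (IP, 3 libraries) was compared with RNA of the unbound fraction (3 libraries), which the sample titles call input. The question the design addresses is which RNAs the tagged ribosomes hold at a higher or lower level than the rest of the tissue RNA. The IP libraries held 32471045 to 46293837 gene counts and the unbound libraries 32926146 to 40768577. Levels are CPM after TMM scaling, given as mean ± SD.

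Lhx5 itself rose from 3.39 ± 2.51 CPM in unbound RNA to 61.8 ± 7.59 CPM in IP RNA (n = 3 each), an 18.1-fold difference, and every IP library lay above every unbound library. Of the 14 other tested transcription factors of the mammillary and premammillary list 8 rose, among them Foxb1 (26.3-fold) and Sim1 (15.6-fold), though the list with Lhx5 passed camera only with the preset correlation (adjusted p = 0.434 with an estimated one). Slc17a6, the vesicular transporter of glutamatergic neurons, rose too (4.24-fold). Markers of astrocytes, oligodendrocytes and their precursors, and microglia fell, with list medians between -3.64 and -3.00 on the log2 scale (adjusted p = 0.437 for each with an estimated correlation). Of the 11 listed long noncoding RNAs that were tested 9 fell, among them Malat1 (25.3-fold lower in IP), and 1 rose (adjusted p = 0.437 with an estimated correlation). Gad1 and Gad2, the enzymes that make GABA, fell by 1.77 and 1.47 on the log2 scale.

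Lhx5 lies on the plus strand of chromosome 5 from 120431699 to 120441223 (mm10). Its log2 fold change was 4.18 ± 0.49 (SE; adjusted p = 8.2e-04, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). Without unbound replicate 3, where it stood at 6.28 CPM, the value was 4.98. Reads of the gene cannot be told from any reads of the transgene, and an annotated gene, Gm27199, overlaps it. Rpl10a, which encodes the tagged ribosomal protein, stood at 6.57 ± 0.79 CPM in IP and 8.58 ± 0.71 CPM in unbound RNA, a log2 fold change of -0.38 that did not pass (adjusted p = 0.139, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). It passed as lower when libraries were scaled on pan-neuronal markers, at -0.91 (adjusted p = 0.00480 in the same edgeR test with Benjamini-Hochberg adjustment). Ribosomal protein genes have many near-identical pseudogenes, and reads aligning to several places were not counted, so these levels are uncertain.

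Of 16991 genes tested, 3586 were higher and 3943 lower in IP, and 1015 and 3053 of these by 2-fold or more. Groups did not overlap for 9492 genes, 55.9% of those tested, against 10% by chance. The share of calls that were higher, 47.6%, depended on how the libraries were scaled. Scaling on pan-neuronal markers gave 815 higher and 7168 lower (10.2% higher) and lowered the median of all genes by 0.53. Over the 15370 genes tested both with and without a GC correction, the test without it gave 3494 higher and 3212 lower (52.1% higher). Removal of the GC trend gave 5123 and 2611 for these genes (66.2% higher) and raised their median by 0.21, and the same correction with each library's mean kept, chosen after a shift was seen, gave 3399 and 3232 (51.3% higher). The lane 2 libraries alone, 2 per group, gave 1297 higher and 2538 lower (33.8% higher), and lane 4, with 1 library per group, has too few for a test of its own.

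**Figure D1:**
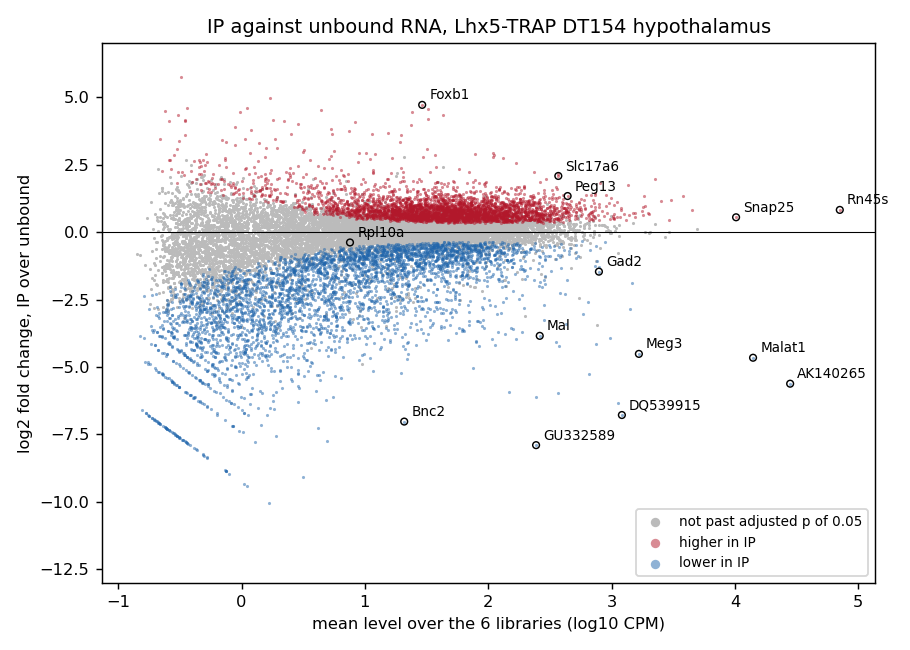
Log2 fold change of IP over unbound RNA (vertical axis) against the mean level over the 6 libraries (horizontal axis, log10 CPM) for the 16991 genes tested, with 3586 called higher in red and 3943 called lower in blue. The diagonal streaks at low level are features with few or no counts in IP, whose fold depends on the prior count.

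Among the largest rises by the rule fixed beforehand were Foxb1 (4.72), Fezf1 (4.55), Samd3 (4.46), Trh (4.36), Lhx5, Eomes (4.08), Sim1 (3.96), Insm2 (3.82), Dmrta2 (3.74), Uncx (3.67) and Otp (3.63), as log2 fold changes. Trh encodes thyrotropin-releasing hormone and stood at 82.1 ± 38.3 CPM in IP against 4.02 ± 3.41 CPM in unbound RNA. Without unbound replicate 3 Foxb1 was at 5.43 and Uncx at 4.84, but Fezf1 was at 3.99, Trh at 3.81, Sim1 at 3.73 and Otp at 3.39. In that library Fezf1 stood at 0.24 CPM and Trh at 0.48 CPM, their lowest levels among the unbound libraries. Without unbound replicate 1 Fezf1 was at 5.53, Samd3 at 5.09 and Trh at 5.13. Fezf1 and Trh did not pass without unbound replicate 2 (4.52, adjusted p = 0.0519, and 4.41, adjusted p = 0.0639, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment).

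Among 15 tested transcription factors of the mammillary and premammillary list, 9 rose and 1 fell, and 11 rose and 1 fell adjusted over the list alone. The list median was 2.77 (camera adjusted p = 1.2e-04; adjusted p = 0.434 with an estimated correlation). Lhx5 is itself a member, and the 14 others, of which 8 rose and 1 fell, had a median of 2.43 (camera p = 9.1e-05; p = 0.0602 with an estimated correlation, neither adjusted over lists). Sim1 stood at 44.2 ± 9.64 CPM in IP against 2.83 ± 1.03 CPM in unbound RNA, and Otp at 9.95 ± 1.5 CPM against 0.80 ± 0.38 CPM. Emx2 rose by 1.44, and Lmx1a, at 0.47 CPM in IP, was the member that fell, a call lost when any library but IP replicate 3, without which it was at -2.67, was left out (adjusted p 0.0573 to 0.110, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). Without unbound replicate 3, in which Lhx1 stood at 12.6 CPM, 13 of 15 members rose and 0 fell, and the value of Lhx1 went from 2.77 to 4.48. Lhx1 did not pass over all genes (adjusted p = 0.0551) but did with the replicate number as a block (3.39, adjusted p = 0.00749, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). The other regional transcription factors of the hypothalamus went both ways. Of 22 tested, 5 rose, Fezf1 (4.55), Bsx (3.46), Pou2f2 (2.04), Tbx3 (1.68) and Zic1 (0.97). Prox1 (-2.52) and Six3 (-1.25) fell, with the same counts adjusted over the list alone. Their median was -0.91 and their mean -0.31, while camera gave the direction as up (adjusted p = 0.537). Without unbound replicate 3, 6 rose and 12 fell of 23 tested. Under pan-neuronal scaling Zic1 (0.42), Bsx (2.90) and Tbx3 (1.13) did not pass, and Tbx3 also did not without IP replicate 3 (1.36). That scaling left 2 rises and 5 falls with a median of -1.44. The list then passed camera (adjusted p = 0.0147, preset correlation). Camera compares it with other genes, whose median this scaling also lowered, so passing does not by itself show a fall. The direction under this scaling is not given here. Six3 lost its call in 9 of the 22 alternative fits.

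Of 29 neuropeptide genes tested, 4 rose and 2 fell, or 4 and 0 adjusted over the list alone. Adcyap1, which encodes the peptide PACAP, rose from 24.9 ± 8.64 to 192 ± 26.6 CPM, and Nms, Pnoc and Trh rose as well. With the replicate number as a block 8 rose and 2 fell, since Nts (2.07), Tac1 (1.23), Ghrh (1.15) and Sst (0.51) passed as well and Gnrh1 (-1.72) fell in place of Cck. Cck (-1.06) and Vip (-1.84) fell, but each lost its call in 11 of the 22 alternative fits, including each one that left out a library other than unbound replicate 3 (-1.10 to -0.76 and -2.03 to -0.98). Nms was at 3.95 without unbound replicate 1 and at 2.90 without unbound replicate 3, against 3.30 with all libraries. Pnoc did not pass under pan-neuronal scaling, nor Trh without unbound replicate 2. The list median was -0.05, its mean 0.03 and its camera adjusted p 0.242. Under pan-neuronal scaling the median was -0.63 with 3 rises and 5 falls. The list then passed camera (adjusted p = 0.00122, preset correlation). Camera compares it with other genes, whose median this scaling also lowered, so passing does not by itself show a fall. With the main scaling camera gave the direction as up, and the direction under pan-neuronal scaling is not given here. Avp, Oxt, Hcrt and Pmch, peptides of the paraventricular, supraoptic and lateral hypothalamus, were each at or below 0.144 CPM in unbound replicate 3 and did not pass the test. Without that library 7 peptide genes rose and 10 fell of 30 tested.

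Of 7 glutamatergic markers 1 rose, both over all genes and adjusted over the list alone: Slc17a6, from 141 ± 47.6 to 599 ± 67.7 CPM (log2 2.08 ± 0.24). The list median was -0.87 (camera adjusted p = 0.796), and the list had 2 rises and 3 falls without unbound replicate 3, and 1 rise and 2 falls with the replicate number as a block. Of 9 GABAergic markers, Gad1 and Gad2 fell and the rest did not pass, with the same 2 adjusted over the list alone. The GABAergic median was -1.38 (camera adjusted p = 0.138), and without unbound replicate 3 it was -1.87 with 8 falls (camera adjusted p = 4.6e-04 with the preset correlation). With all 6 libraries the adjusted p was 0.778 with an estimated correlation. Of 10 monoaminergic and cholinergic markers, Hdc (-1.86), Th (-3.48) and Slc18a2 (-1.93) fell, also adjusted over the list alone, with a list median of -1.90 (camera adjusted p = 0.138). Th and Slc18a2 rested in part on unbound replicate 3, where they stood at 48.5 and 69.1 CPM. Without it they were -1.93 and -1.002, the list had 5 falls and its median was -0.88. Neither passed when any IP library was left out, and with the replicate number as a block they did not pass (-2.80, adjusted p = 0.0757, and -1.62, adjusted p = 0.0718, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). Hdc did not pass without IP replicate 1 or 2 or unbound replicate 1 (-1.86 to -1.43).

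Receptors for hormones, peptides and amines rose in 19 of 39 cases and fell in 2, with the same counts adjusted over the list alone. Galr1 (2.72), Esr1, the estrogen receptor alpha (1.62), Oprl1 (1.26) and Adra2a (1.22) had the smallest adjusted p, and Insr (-0.81) and Lepr (-1.39) fell. Lepr did not pass when any library but unbound replicate 2 was left out (adjusted p 0.0538 to 0.0762, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment), and with the replicate number as a block the list had 22 rises and 1 fall. The list median was 0.66 (camera adjusted p = 5.5e-04; adjusted p = 0.516 with an estimated correlation), and under pan-neuronal scaling it was 0.13 with 8 rises and 4 falls. Of 20 pan-neuronal markers, 12 rose and 1, Map2, fell, or 13 and 1 adjusted over the list alone. Map2 (-0.66) did not pass with the GC trend removed (-0.39, adjusted p = 0.0720), with that and the replicate block (-0.38, adjusted p = 0.0580) or with the lane 2 libraries alone (-0.56, adjusted p = 0.0970, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). The list median was 0.55 (camera adjusted p = 0.00122; adjusted p = 0.434 with an estimated correlation). Gap43 (1.01), Stmn3 (1.24), Uchl1 (0.86) and Tubb3 (0.91) were among the rises. By construction pan-neuronal scaling brought the median to 0.02, with 2 rises and 1 fall, and Uchl1 and Tubb3 did not pass.

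Of 18 astrocyte markers 17 fell (median -3.00), of 16 oligodendrocyte markers 16 fell (median -3.64), of 10 precursor markers 9 fell (median -3.02) and of 15 microglia markers 14 fell (median -3.23), all with the same counts adjusted over the list alone. The camera adjusted p-values were 4.1e-07, 1.1e-08, 3.7e-05 and 5.1e-06 (each adjusted p = 0.437 with an estimated correlation). Mal, a gene of myelinating cells, went from 489 ± 122 CPM in unbound to 34 ± 9.49 CPM in IP RNA, and Opalin, Fgfr3, Gjb6, Tyrobp and C1qb also fell. Aldoc and C1ql1 were among the members that did not pass, at -0.45 and -0.38. Of 14 vascular markers 9 fell, or 10 adjusted over the list alone (median -2.62, camera adjusted p = 2.3e-04; adjusted p = 0.516 with an estimated correlation). Of 14 ependymal and tanycyte markers 11 fell, and adjusted over the list alone 11 fell and 1, Gpr50, rose (median -2.59, camera adjusted p = 4.6e-04; adjusted p = 0.434 with an estimated correlation). Over all genes Gpr50 did not pass (1.98, adjusted p = 0.0530) but did with the replicate number as a block (2.35, adjusted p = 0.0251, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). Dio2, a deiodinase of tanycytes, fell by 3.77. Of 7 choroid plexus markers 3 fell, Kcne2, Otx2 and Enpp2, also adjusted over the list alone (median -2.12, camera adjusted p = 0.132). Kcne2 did not pass without IP replicates 1 or 2 or either of unbound replicates 1 and 2, Otx2 without IP replicates 1 or 3, and Enpp2 without IP replicates 1 or 3 or unbound replicates 1 or 2 (adjusted p 0.0507 to 0.0685, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). Otx2 was at -0.79 without unbound replicate 3, against -1.38 with it. Ttr, the main choroid plexus transcript, was at 30.7 CPM in unbound replicate 3 and at 1961 and 2156 CPM in the other unbound libraries, and without that replicate 8 of 8 choroid plexus markers fell.

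**Figure D2:**
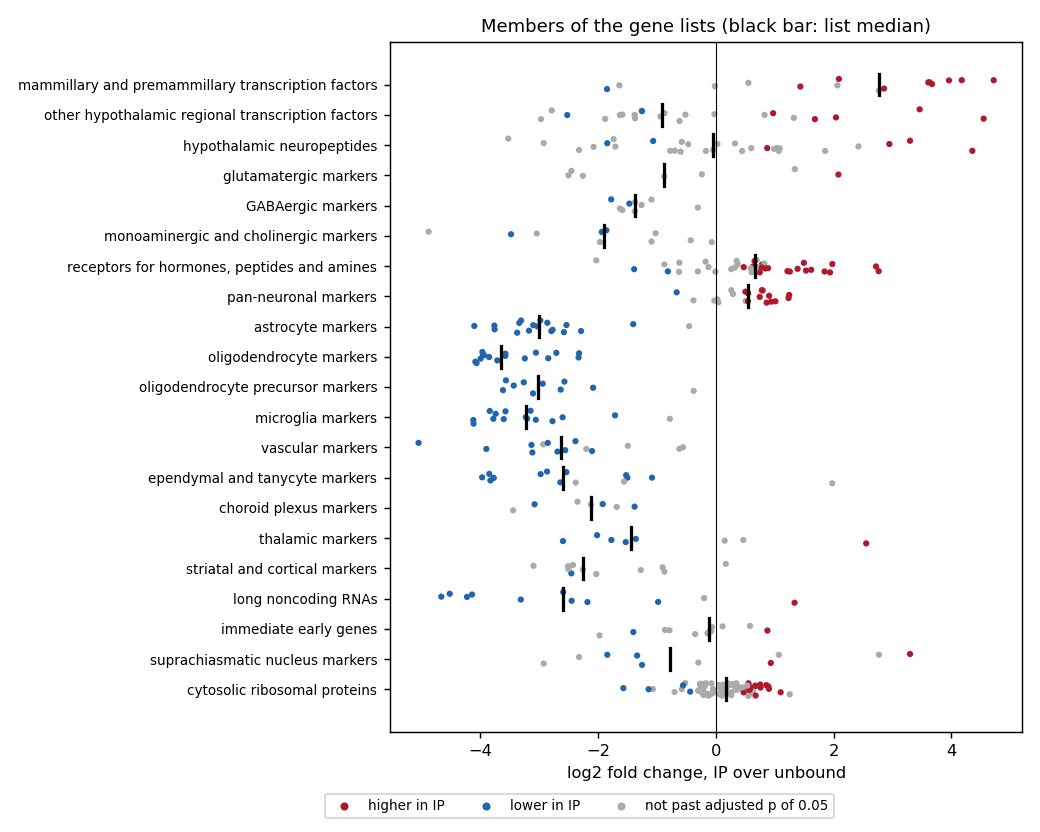
Log2 fold change of IP over unbound RNA for each tested member of the 21 lists with at least 3 tested members, coloured by direction where the adjusted p was under 0.05, with a black bar at each list median. The 4 glial lists have medians between -3.64 and -3.00, and the mammillary and premammillary list has a median of 2.77.

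Of 8 thalamic markers 5 fell, led by Plekhg1 (-2.59) and Prkcd (-2.01), and 1, Calb2, rose by 2.55, with the same counts adjusted over the list alone (median -1.44, camera adjusted p = 0.132). Of 11 striatal and cortical markers 1, Rgs9, fell, and 0 adjusted over the list alone (median -2.26, camera adjusted p = 0.416). Ppp1r1b, a striatal phosphoprotein gene, stood at 19.6 CPM in unbound replicate 3 against 567 and 487 CPM in the others, and without that library 9 of these 11 markers fell. Rgs9 did not pass when any other library was left out (-2.52 to -2.10), and with the replicate number as a block 2 markers fell and Rgs9 was not among them. Of 10 suprachiasmatic markers 2 rose, Nms and Zfhx3, and 3 fell, Rorb, Six3 and Vip, or 3 and 4 adjusted over the list alone. Zfhx3 lost its call in 8 of the 22 alternative fits, Six3 in 9 and Vip in 11, in each case whenever a library other than unbound replicate 3 was left out (0.74 to 1.06, -1.34 to -0.88 and -2.03 to -0.98). Zfhx3 also lost it under pan-neuronal scaling (0.43). Their median was -0.77 and their mean -0.19, while camera gave the direction as up (adjusted p = 0.921). Without unbound replicate 3, 4 rose and 6 fell of 11 tested. Of 12 immediate early genes Fos rose by 0.88 and Arc fell by 1.40, and adjusted over the list alone 1 rose and 0 fell. Fos did not pass under pan-neuronal scaling (0.34), and Arc lost its call in 10 of the 22 alternative fits, including each one that left out a library other than unbound replicate 3 (-1.55 to -0.97). Their median was -0.12 and their mean -0.35, while camera gave the direction as up (adjusted p = 0.921), and without unbound replicate 3 there were 7 falls and 1 rise.

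Of 11 tested members of the noncoding list 9 fell and 1 rose, also adjusted over the list alone (median -2.59, camera adjusted p = 1.5e-04; adjusted p = 0.437 with an estimated correlation). Malat1 went from 26969 ± 3578 to 1067 ± 308 CPM, and Meg3 (-4.52), Miat (-4.22) and Snhg11 (-4.14) fell by similar amounts. Peg13 was the member that rose, by 1.34, but it lies within Trappc9, which also rose (0.65), and reads of the genes may be mixed. Of the 699 tested genes of long noncoding biotype 61 rose and 170 fell (8.7% higher and 24.3% lower, against 23.5% and 20.7% of protein-coding genes). Of 1519 tested features named by an mRNA accession 96 rose and 690 fell. Most of the largest falls were features named by an mRNA accession, with no gene name in the annotation used, such as GU332589 (-7.90), DQ539915 (-6.78), X57780 (-6.35) and AK140265 (-5.62). AK140265 was the most abundant of them, at 54912 CPM in unbound RNA. The protein-coding genes among these falls were Bnc2 (-7.03) and Tal1 (-6.13), which stood at 110 and 29.7 CPM in unbound replicate 3. Without that library their values were -4.52 and -3.16, and neither passed when any IP library was left out (Bnc2 was at -7.87 without IP replicate 3).

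Of 78 cytosolic ribosomal protein genes 15 rose and 4 fell, and adjusted over the list alone 0 rose and 0 fell. The list median was 0.18 (camera adjusted p = 0.0741). It passed as up without the low-count filter, without the third pair, and without IP replicate 2 or 3 or unbound replicate 1 or 3 (medians 0.20 to 0.28, camera adjusted p 0.00416 to 0.0288 with the preset correlation; with all 6 libraries adjusted p = 0.896 with an estimated one). It turned to -0.35 under pan-neuronal scaling, with 0 rises and 29 falls. Rps27l, Rpl15, Rpl41 and Rpl35 rose, and Rpl9, Rps12, Rps4x and Rpl22 fell. Rpl15 did not pass without unbound replicate 2, Rpl41 without IP replicate 1 and Rpl35 without either (0.47 to 0.77), Rps4x without IP replicates 1 or 2 or unbound replicate 1, and Rpl22 without IP replicates 2 or 3 or unbound replicates 1 or 2 (-0.58 to -0.33). Rn45s, Snap25, Mir6236 and Vsnl1 were among the most abundant features in IP RNA. Vsnl1, a neuronal calcium sensor gene, rose by 1.33 and Snap25 by 0.55, though Snap25 did not pass under pan-neuronal scaling (0.02, adjusted p = 0.906) or with the lane 2 libraries alone (0.56, adjusted p = 0.104, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). Of the pituitary list 1 member was tested (Tshb, -1.25, not passed), and of the mitochondrial list 0, so neither list has a test.

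**Figure D3:**
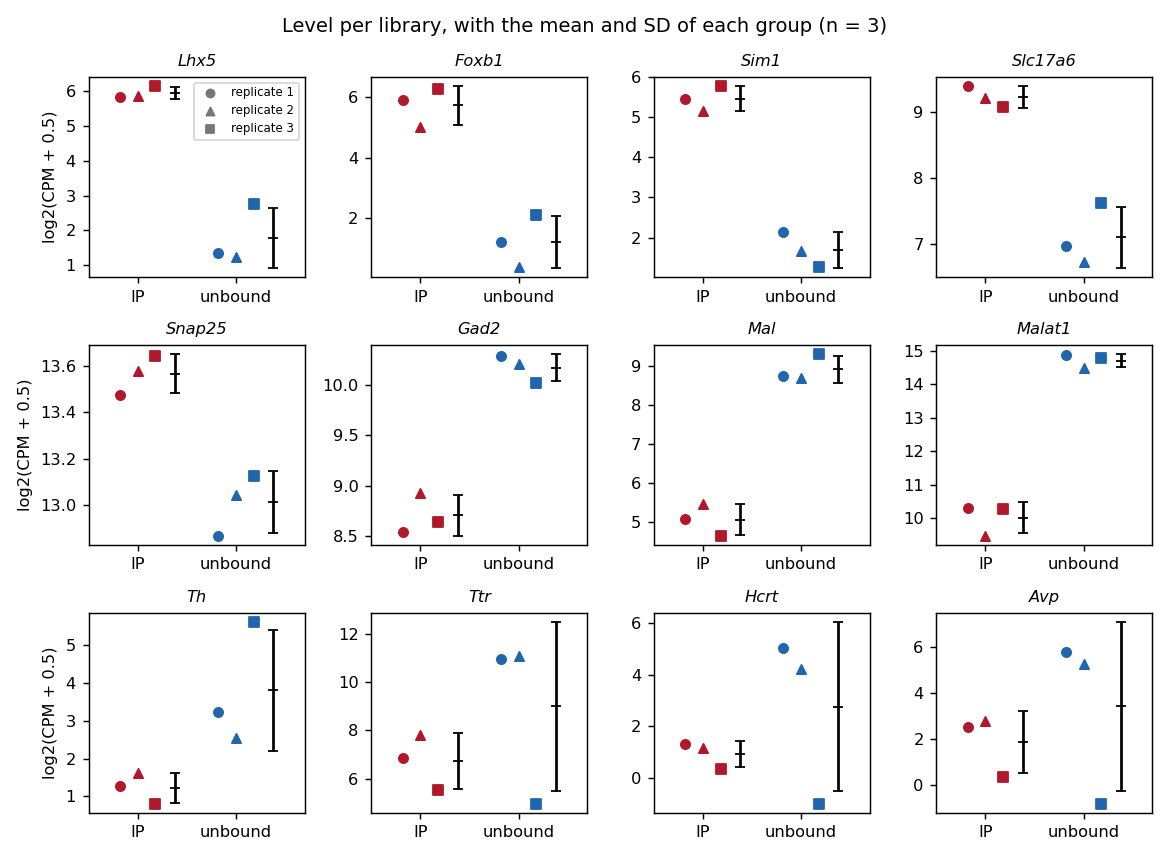
Level of 12 genes in each library, as log2(CPM + 0.5) on the vertical axis with its own range in each panel, with IP in red, unbound in blue, replicates by symbol, and the mean and SD of each group (n = 3) beside them. In unbound replicate 3, Th is at 48.5 CPM and Ttr at 30.7 CPM.

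With the replicate number as a block, Cck (-0.95, adjusted p = 0.0540), Lepr (-1.29, adjusted p = 0.0518), Kcne2 (-2.75, adjusted p = 0.0840) and Rgs9 (-2.03, adjusted p = 0.0949) did not pass edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Nothing in the labels says that the replicates came from separate animals, so p-values measure only the spread between these samples. All IP libraries carried one index sequence and all unbound libraries another, so index and group cannot be told apart.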

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

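The tests in this part were chosen after the result was seen, except the comparison of long noncoding with protein-coding genes, whose bound was written before. The test of midbrain and hindbrain genes was first run on the 4 of its 10 genes that pass the count filter and then on all 10. The verdict on the noncoding class was changed from excluded to open once an interval had been computed for it. Reads that aligned to more than 1 place, which the comparison of genes does not use, made up 44.5% of IP reads and 32.5% of unbound reads, and every IP library lay above every unbound library. Rn45s, the ribosomal RNA precursor, took 8.74% of gene counts in IP and 5.28% in unbound RNA.

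Of the 11 listed long noncoding RNAs that were tested 9 fell (adjusted p = 0.437 with an estimated correlation), while of the 699 genes of that biotype 170 fell and 61 rose. Scaling is argued against, since the highest median of the list over the scalings was -2.59. RNA outside polysomes, kept in the unbound fraction, may account for it, but genes of long noncoding biotype as a class lay only 0.37 below protein-coding genes (difference -0.37, 95% bootstrap interval -0.52 to -0.27), which does not reach a bound of -0.5 set beforehand except at the edge of the interval. The 1597 tested features with no GENCODE match, whose median was -1.12, belong to neither class. The long noncoding class holds many weakly expressed genes, and whether the explanation covers the abundant RNAs stays open. Loss of non-neuronal cells stays open too, since Meg3, Miat, Snhg11 and Rian, whose median was -4.18, were picked after the result and mostly from the strongest falls.

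Unbound replicate 3 stood apart from the other unbound libraries. It held 24.3 CPM of Tph2, 49.8 CPM of Slc6a3 and 14.8 CPM of Pax7, genes of midbrain and hindbrain neurons. In it 10 genes of those regions had a median log2 ratio of 2.93 to the other unbound libraries (median 1.55 over the 4 first tested). Of the 10, 7 were above 2-fold and 1, Nr4a2, went the other way (-1.04), at 24.2 CPM against 48.3 and 52.2 CPM in unbound replicates 1 and 2. A swap with an IP library is argued against, since 100% of the oligodendrocyte markers lay above every IP library in it. Of 174 genes at least 4-fold apart in this library, 87.4% deviated the same way in IP replicate 3, against 44.3% and 19.0% in IP replicates 1 and 2, so a dissection shared by the third pair is a candidate explanation. The deviations of the IP libraries depend on each other, so the lower shares in IP replicates 1 and 2 are not independent of that in IP replicate 3. Of the 174, 155 were lower in unbound replicate 3 and 19 higher. In IP replicate 3 the 10 midbrain and hindbrain genes showed no gain (median log2 ratio of 0.00 to the other IP libraries, 0 above 2-fold). This cannot tell whether the third IP sample held such tissue. IP RNA comes from tagged cells, and most of the 10 genes were near the floor in IP. Pax7, outside the 10, stood at 3.71 CPM in IP replicate 3 against 2.23 and 1.06 CPM in IP replicates 1 and 2.

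The 73 markers of the 5 lists of glial and vascular cells stayed in IP at a median of 11.7% of their unbound level, with 16.6% for the 14 vascular ones. Carry-over of all unbound RNA alike at that level is argued against, since it would leave every abundant feature at least that share. The 10 abundant features with the lowest share, picked for it, kept a median of 1.63%. Carry-over that differs between RNAs was not tested. The 5 lists differed in log2 fold change (Kruskal-Wallis permutation p = 0.0231, 73 genes). The permutation treats these genes as independent, which they are not. The test therefore cannot decide whether non-specific binding of ribosomes, alike for all non-neuronal cells, is the whole account. Unequal binding of ribosomes, and expression of some markers in the tagged cells, stay open and were not tested.

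Of the 10 splits of the 6 libraries into groups of 3, 1 gave as many genes as the real one, the real one itself, with 7529 genes. The highest of the other splits was 0, by edgeR's quasi-likelihood test, with 25 to 692 genes at an unadjusted p under 0.05. The design has too few splits for a share under 0.05. Each other split also mixed IP and unbound libraries within its groups, which widens the spread that the test uses. Their 0 calls therefore do not argue against chance. Among the 4 splits that part all 3 pairs, the others also called 0 genes.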

How the results depend on the processing

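Across 22 alternative fits and the other list tests no call of a list or a named gene was reversed. Named genes kept their side of the threshold in 2170 comparisons with an alternative, lost it in 177 and gained it in 3, and lists kept it in 476, lost it in 10 and gained it in 17. The counts that moved by over 1.5 times were as follows, and where no cause is named the cause was not tested. With pan-neuronal scaling, which lowers every value, 815 genes were higher and 7168 lower, 251 and 4845 by 2-fold or more. With the GC trend removed (15370 genes), 2611 were lower, and 1741 were higher and 1977 lower by 2-fold or more, against 3212, 962 and 2359 for the same genes uncorrected, so part of the move is the gene set. With the GC trend removed together with the replicate block, 5631 were higher, and 1756 were higher and 1934 lower by 2-fold or more. The block alone gave 3952 higher and 4017 lower and ended the calls of Th, Slc18a2, Cck, Lepr, Kcne2 and Rgs9, while Lhx1, Gpr50 and other genes outside the rule passed with it. The lane 2 libraries, chosen after seeing the data and fewer in number, gave 1297 higher and 2538 lower. The glmTreat test against a fold of 1.2, a lower bar than 2-fold, gave 2652 higher. Camera with an estimated correlation called 0 lists against 10. With each library left out, higher calls ranged from 2489 to 4139 and lower calls from 3263 to 4448, those of 2-fold or more from 781 to 1347 and from 2723 to 3331, and lists called from 10 to 14. Without the third pair, chosen after seeing the data, 4429 were higher and 4649 lower. Genes with few counts are limited by depth. A 2-fold change was recovered in 39% of simulated cases. That simulation changed far fewer genes than were called here, which makes the adjusted threshold stricter. It drew the changed genes only from those above a minimum mean level and did not part genes by count. The 39% is therefore no measure of the limit for genes with few counts.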

Other observations

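The list of imprinted genes and its test were chosen after the result was seen, and the test of genes next to Lhx5 was written before. Imprinted protein-coding genes, expressed from 1 parental allele and many of them abundant in the hypothalamus, were mostly higher in IP. Of 26 tested, 18 rose and 2 fell, with a median log2 fold change of 1.07. Peg10 (2.16), Nap1l5 (1.95), Magel2 (1.89), Ndn (1.86) and Calcr, the calcitonin receptor (2.77), rose. Igf2 fell by 4.03 and Cdkn1c by 1.39. Since members were seen to be high before the list was made, its camera p (0.0333 with an estimated correlation) restates that choice and supports no explanation. The median was 0.57 under pan-neuronal scaling.

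Extra copies of the Lhx5 region in the tagged line stay open, because both groups come from that line and copies would be present in both. The 7 tested genes within 200 kb had a median of 0.35, below the bound of 0.5 set beforehand, but for this reason the bound decides nothing. Plbd2 (0.85) and Rita1 (0.77) rose, and Tpcn1 fell by 1.78.

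Other genes chosen after their values were seen were Trp73, at 8.89 ± 1.67 CPM in IP and 1.36 ± 0.40 CPM in unbound RNA (n = 3), and Reln, at 27.7 ± 12.7 and 38.7 ± 8.84 CPM. Yeats2 varied within IP, at 86.8, 184 and 320 CPM in replicates 1, 2 and 3, against 22.03, 23.8 and 34.8 CPM in unbound RNA.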
